A study of Homo sapiens with 12 samples.

How the data were processed

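RNA from 12 xenograft tumours was sequenced by the authors as 3' tag libraries (Lexogen QuantSeq 3' FWD, strand-specific, 50 ng of RNA, 18 PCR cycles, single reads of 75 nt on a NextSeq 500). The submitters' processing notes name BWA for alignment, featureCounts for the counts per gene and edgeR, with no versions, and the human genome build GRCh38 (hg38). Whether reads from the mouse host were removed, and which annotation release was used, is not given in the sources used here. The deposited values are raw counts per gene, not normalised by the authors. The table held 43836 genes, of which 20013 had no count in any library. Each of its 12 columns was matched to a sample by the 3-digit serial number that the column name shares with 1 sample title, and 0 columns were left over. Gene positions and symbols come from GENCODE release 29: 43564 identifiers matched without the version, 40863 of them identical with the version, and 272 matched no gene. Before any test 517 genes (XIST, TSIX and the genes of the Y chromosome) were left out, at most 0.204% of the counts of a library.

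The groups were vehicle, CEP-1347 and URMC-099, with 4 libraries each, taken from the treatment in the labels. The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group kept 16406 genes (12959 protein-coding and 2204 pseudogenes), TMM factors scaled the libraries, and a quasi-likelihood fit with robust dispersion compared the groups in 1 model without covariates. The common dispersion was 0.338 (biological coefficient of variation 0.582), with 9 residual degrees of freedom and a median of 14.5 prior degrees of freedom. All tests were two-sided. The p of each comparison was adjusted by the Benjamini-Hochberg method over all tested genes, and a gene or list passed at an adjusted p under 0.05. The contrasts were CEP-1347 against vehicle, URMC-099 against vehicle, URMC-099 against CEP-1347, and the mean of the inhibitor groups against vehicle. Library totals and composition were compared between groups by exact permutation tests of the difference of means, 18 in all.

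Levels are TMM-normalised counts scaled to library size (CPM), and log2 CPM use a prior count of 2. The 95% intervals of log2 fold changes come from the edgeR fit. The total counts per library, 14889163 to 23038422, set a floor of 3 counts, or 0.130 to 0.201 CPM in a library and 0.0392, 0.0381 and 0.0367 CPM over the vehicle, CEP-1347 and URMC-099 groups. A fold against a group with 0 counts is given as a lower bound at this floor over the group. The libraries are PCR products, and molecular identifiers are not mentioned in the sources used here, so floors cover counting error only.

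Of 36 gene lists, 34 had at least 5 tested members and were tested. They covered the MLK and neighbouring kinases, the AP-1 and immediate-early genes, ERK output, NF-kB targets, interferon genes, MHC class I, mitosis, G1/S, p53 targets, the BCL2 family and caspases, hypoxia, glycolysis, cholesterol synthesis, the lysosome, the unfolded protein response with ATF4 targets, heat shock, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes and ribosomal proteins. Others marked basal and luminal epithelium, mesenchymal transition, metalloproteinases, YAP/TAZ, TGF-beta, Notch and Wnt, and NRF2 targets, fibroblasts, endothelium and pericytes, myeloid cells, adipocytes, skeletal muscle, red blood cells and liver, and histones. The lymphocyte and xenobiotic lists had too few tested members. All lists are of human genes, so those chosen to mark cells of the mouse host do not measure them directly. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and adjusted over the lists of its comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were the alternatives. List members are also counted by their own edgeR calls, adjusted over all genes and adjusted over the list alone.

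The genes named were, for each comparison, the 10 largest rises and falls among genes with an adjusted p under 0.05, a mean of at least 20 counts per library in the higher group and no overlap between the libraries compared. Where fewer than 5 passed in a direction, the 5 genes of that direction with the smallest p and such a mean were taken as values, of which the text prints some. The MLK genes MAP3K9, MAP3K10, MAP3K11 and MAP3K21 were always taken. From each list that passed, and from the AP-1, mitosis, p53 and BCL2 lists in any case, the rule takes the 4 members with the smallest p in the direction of the list, of which the text prints some. Pseudogenes, genes without a symbol and read-through names were counted and not named. The circadian and glucocorticoid genes and the further muscle genes in the closing section were chosen after their values, or those of related genes, were seen.

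The alternatives were RLE size factors, no filter on low counts, a filter at a mean of 50 counts, DESeq2 1.42.0, limma voom with quality weights, dispersion without the robust step, only the groups compared in the fit, a covariate of host marker levels, and leaving out each library in turn. A covariate of muscle marker levels and a fit of protein-coding genes only were chosen after seeing the data, as were 4 further gene lists. The likeness of the responses was measured across genes beside 100 simulated data sets without change and with the vehicle libraries split 2 and 2. Each comparison was repeated on the 35 distinct splits of its 8 libraries, or on 100 drawn splits of all 12.

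The pipeline was tested on simulated data with 200 of 16406 genes changed. The changed genes were all drawn from genes with a mean of at least 50 counts. The recovery rates therefore do not cover genes with fewer counts. At a 2-fold change it recovered 52.0%, 45.5%, 41.5% and 54.5% of them for CEP-1347, URMC-099, the inhibitors against each other and both against vehicle. At 4-fold it recovered 78.5%, 80.0%, 79.5% and 84.5%, and at 8-fold 88.5%, 92.0%, 86.5% and 93.5%. False calls were 1.19% to 9.57% of the calls. Without any change 0.05 lists passed on average, and an AP-1 list lowered 2-fold was recovered in all of 20 draws. The simulated genes are independent, which real genes are not. Other splits of the real libraries passed 4.68 to 5.71 lists on average, so the simulated rate of false list calls does not describe the real data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the table, ran the exact tests and drew the figures.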

Results

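Bulk RNA was sequenced from 12 tumours of a human triple-negative breast cancer grown as a patient-derived xenograft in the mammary fat pad of immunodeficient NSG mice. Each group held 4 tumours, which the labels call biological replicates. From a tumour volume of 150 mm3, mice received vehicle, CEP-1347 at 1.5 mg/kg or URMC-099 at 7.0 mg/kg daily for 21 days. CEP-1347 is an inhibitor of the mixed-lineage kinase (MLK) family and URMC-099 is an inhibitor developed against MLK3, a kinase of that family encoded by MAP3K11. The libraries held 3' end tags, so each value below is a count of reads near the 3' end of a gene, and the mean ± SD of a group is over n = 4 libraries.

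The total counts were 21602172, 14889163, 21772623 and 17425640 in vehicle replicates 1 to 4. They were 19734347, 16863406, 23038422 and 19236856 with CEP-1347, and 22325689, 20576246, 18002186 and 21923875 with URMC-099. The most counted gene, the mitochondrial gene MT-CO3, took 2.71% to 3.47% of a library. Mitochondrial genes took 7.86% to 9.61% and ribosomal protein genes 10.9% to 13.9%. None of 18 two-sided exact permutation tests of such library summaries between groups passed: the smallest unadjusted p was 0.114 (n = 4 per group; the smallest p this design allows is 0.0286). URMC-099 replicate 3 stood apart on the first principal component, which carried 15.1% of the variance. In it, 124 genes with a mean of at least 50 counts elsewhere had no count, against 8 to 68 such genes in each other library.

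The first comparison, CEP-1347 against vehicle, asks what daily CEP-1347 changes in the RNA of the tumour. NR4A1 fell, the AP-1 and immediate-early genes fell as a group, heat shock genes rose as a group, and skeletal muscle genes fell as a group. With an estimated correlation between genes or by fry 0 of these lists passed. Other splits of the same libraries passed 5.71 lists on average, more than the 3 here. None of the MLK genes passed. The calls for NR4A1 and for the lists depended on single libraries or on how the correlation between genes was treated, as given with each value below.

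With edgeR, 1 gene of 16406 passed an adjusted p of 0.05 with CEP-1347: 0 higher and 1 lower. At an unadjusted p under 0.05 there were 525 genes, 208 higher and 317 lower, against 820 expected by chance. DESeq2 called 6 genes and limma voom 3. The libraries of the groups did not overlap for 190 genes higher and 259 genes lower, against 234 expected by chance in each direction. The gene that fell was NR4A1 (ENSG00000123358.19, GRCh38 chr12:52022832-52059507), an orphan nuclear receptor induced early after a stimulus. Its log2 fold change was -2.29 (SE 0.31, adjusted p = 0.00532), or 4.90-fold lower, with normalised counts scaled to library size (CPM) of 92.5 ± 30.5 with vehicle and 18.9 ± 2.71 with CEP-1347. The adjusted p was 0.0918, 0.0810, 0.109 and 0.0843 without CEP-1347 replicates 1, 2, 3 and 4 in turn, and 0 genes passed in each of these fits. It ranged from 1.1e-09 to 0.0796 over the alternatives that kept all libraries. The log2 fold change moved little, from -2.49 to -2.16 without 1 library in turn and from -2.29 to -2.23 over those alternatives. SGK1 (ENSG00000118515.11, chr6:134169246-134318112), a kinase induced by glucocorticoids, had a log2 fold change of -1.82 (SE 0.34, adjusted p = 0.136), from 36.7 ± 9.68 to 10.4 ± 3.21 CPM. Its adjusted p ranged from 0.00291 to 0.902 over the alternatives other than leaving out a library.

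Of the next genes by p, TNS1, which encodes a focal adhesion protein, stood at 44.5 ± 9.39 CPM with vehicle and 20.9 ± 5.95 with CEP-1347 (log2 fold change -1.09, adjusted p = 0.935). The haemoglobin gene HBA2, which has a near-identical copy in HBA1, stood at 388 ± 136 and 102 ± 45.1 CPM (log2 fold change -1.93). The muscle gene DHRS7C was at 4.36 CPM with vehicle and had 1 count in total with CEP-1347. Among genes with higher values, the transcriptional regulator NACC1 (ENSG00000160877.5, chr19:13118103-13141141) went from 8.25 to 18.7 CPM (log2 fold change 1.18, adjusted p = 0.935). The kinesin gene KIF13A went from 49.9 to 74.3 and the ETS factor gene SPIB from 13.9 to 27.3 CPM. SYTL5, a vesicle traffic gene, had 0 counts with vehicle and 1.03 CPM with CEP-1347, at least 26.2-fold higher against a floor of 3 counts over the group. None of these passed in the edgeR fit with robust dispersion. HBA2 passed without the robust step, by DESeq2 and by limma voom, and DHRS7C passed by DESeq2.

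MAP3K11, the MLK3 gene (ENSG00000173327.7, chr11:65597755-65615382), stood at 20.4 ± 5.9998 CPM with vehicle and 21.6 ± 6.56 with CEP-1347, a log2 fold change of 0.08. The MLK1 gene MAP3K9 (chr14:70722526-70809534) stood at 1.67 and 1.59 CPM, the MLK2 gene MAP3K10 (chr19:40191744-40215575) at 2.70 (1.73 without vehicle replicate 2) and 2.67, and the MLK4 gene MAP3K21 (chr1:233327768-233385148) at 4.49 and 3.46. The sign of the change was not the same in every alternative for MAP3K9, MAP3K10 or MAP3K11. The list of MLK and neighbouring kinases had a median log2 fold change of -0.03 (camera, adjusted p = 0.526).

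Of 34 gene lists, 3 passed with CEP-1347 by camera with a preset correlation: 1 higher and 2 lower. By fry and with an estimated correlation 0 passed. The AP-1 and immediate-early list had a median log2 fold change of -0.52, with 24 of 27 genes lower (adjusted p = 1.1e-08; adjusted p = 0.277 with an estimated correlation). Of its genes, 1 fell after adjustment over all genes and 4 when adjusted over the list alone, and 1 of its 27 genes is also in another list. Among them the zinc finger factor KLF4 was at 21.96 CPM with vehicle and 5.15 with CEP-1347 (log2 fold change -2.08), and EGR1 (chr5:138465490-138469315) was at 133 ± 61.1 and 49.0 ± 20.1 (-1.44). JUNB was at 245 and 167 CPM (-0.55). The list median was -0.33 without CEP-1347 replicate 1, still past the threshold. The heat shock list, of protein-folding chaperones, rose with a median of 0.30 and 17 of 19 genes higher (adjusted p = 0.000383; adjusted p = 0.391 with an estimated correlation). No member passed alone. The cochaperone STIP1 was at 139 and 180 CPM and HSP90AA1 at 673 and 828. Without CEP-1347 replicate 2 the heat shock median was 0.18 (adjusted p = 0.0439).

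The skeletal muscle list fell with a median log2 fold change of -5.56, also -5.56 with members at the floor set to their bound, and all 15 genes lower (adjusted p = 3.7e-12; adjusted p = 0.277 with an estimated correlation). After adjustment over all genes 0 of its members fell, and 12 did when adjusted over the list alone. None of its genes is in another list. With vehicle 14 of the 15 were over 1 CPM, with CEP-1347 4, and with URMC-099 11. The giant sarcomere gene TTN was at 104 ± 133 CPM with vehicle and 0.472 with CEP-1347, and the thin filament gene NEB at 12.3 and 0.118. The myosin light chain gene MYLPF was at 25.2 and 0.203 CPM, and the myosin gene MYH2 was at 12.8 ± 15.0 with vehicle against 1 count in total with CEP-1347, a gene that passed by DESeq2. The mean log2 CPM of the list was 5.40, 3.07 and 4.07 in vehicle replicates 1, 3 and 4 and -1.88 in vehicle replicate 2, so the level varied by tumour within the vehicle group. Without vehicle replicate 1 the vehicle means of TTN, NEB, MYLPF and MYH2 were 39.8, 2.83, 13.7 and 5.66 CPM. With CEP-1347, TTN and NEB were at 0.0782 and 0.0374 without CEP-1347 replicate 1 and MYLPF at 0.0172 without CEP-1347 replicate 4. These NEB and MYLPF values lie under the floor of 0.0381 CPM over the CEP-1347 group, so they rest on fewer than 3 counts. The call ended with the muscle marker covariate, which is built from the list itself (median 0.34).

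The mitosis list had a median of 0.14 with CEP-1347 (adjusted p = 0.0815), with KIF2C, a mitotic kinesin, at 22.3 CPM with vehicle and 34.8 with CEP-1347. The p53 target list had a median of 0.11 (adjusted p = 0.213), with FDXR at a log2 fold change of 0.35 and the cell cycle inhibitor gene CDKN1A at 0.28. The BCL2 family and caspase list had a median of 0.11 (adjusted p = 0.0808), with the pro-apoptotic gene BMF at 0.963 and 3.56 CPM and APAF1 at a log2 fold change of 0.76. These lists did not pass by camera with the preset correlation. Of the alternatives that kept all libraries, the mitosis list passed by limma voom and with the muscle marker covariate (adjusted p from 0.0171 to 0.918) and the BCL2 family list with only the groups compared (0.0498 to 0.294). The mitosis list also passed without vehicle replicate 2 (adjusted p = 0.0329) and without CEP-1347 replicate 3 (median 0.28, adjusted p = 2.3e-06), and the BCL2 family list without vehicle replicate 2 (adjusted p = 0.0335). The mitosis median was 0.07 without vehicle replicate 3 and 0.05 and 0.06 without CEP-1347 replicates 1 and 2 (adjusted p = 0.266, 0.684 and 0.274). That of the p53 targets ran from 0.03 without CEP-1347 replicate 3 to 0.19 without vehicle replicate 2. The number of lists that passed was 6 without vehicle replicate 2, 8 without vehicle replicate 4, 5 without CEP-1347 replicate 2 and 11 without CEP-1347 replicate 3.

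**Figure D1:**
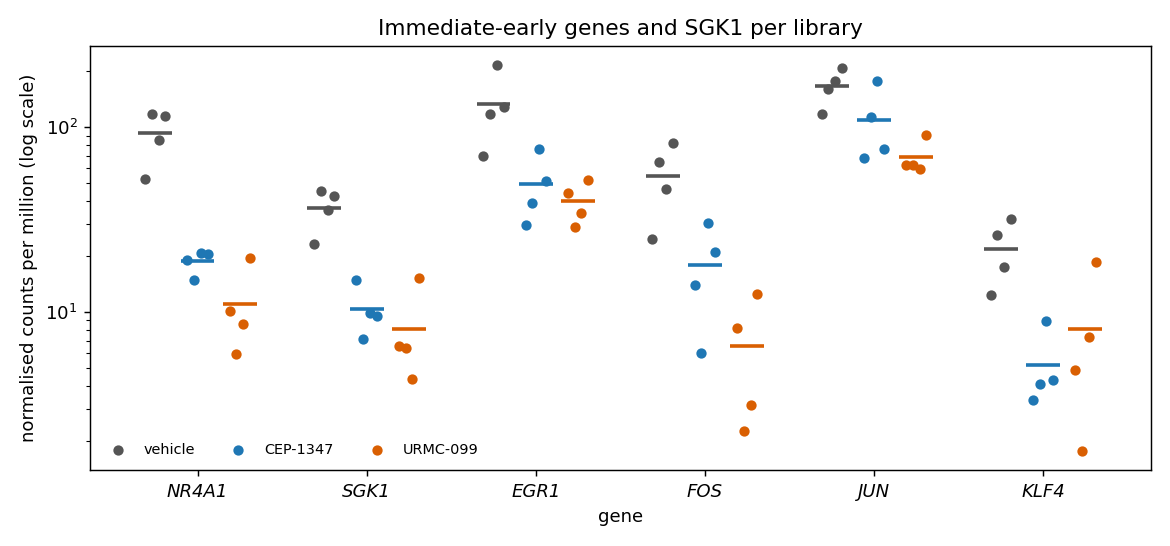
Normalised counts in CPM (log axis) of NR4A1, SGK1, EGR1, FOS, JUN and KLF4 in each library of the vehicle, CEP-1347 and URMC-099 groups; points are libraries and bars are group means. NR4A1 lies between 52.4 and 117 CPM with vehicle, between 14.9 and 20.7 with CEP-1347 and between 5.90 and 19.6 with URMC-099.

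The second comparison, URMC-099 against vehicle, asks the same of URMC-099. NR4A1 and SGK1 fell. The AP-1 and immediate-early genes fell as a group, with FOS and JUN lower as values, and so did hypoxia, fibroblast, mesenchymal and TGF-beta genes. These calls hold for a preset correlation between genes, and 0 lists passed with an estimated correlation. Genes of oxidative phosphorylation, mitosis, heat shock, ribosomal proteins, the NRF2 response, the interferon response and the basal epithelium rose as groups by small amounts. With an estimated correlation 0 of these passed either, and all but the oxidative phosphorylation and NRF2 lists lost their call without some single libraries. None of the MLK genes passed.

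With edgeR, 2 genes passed with URMC-099, 0 higher and 2 lower. At an unadjusted p under 0.05 there were 965 genes, 424 higher and 541 lower, against 820 by chance. DESeq2 called 24 genes and limma voom 1. The groups did not overlap for 263 genes higher and 292 lower, against 234 by chance in each direction. NR4A1 fell with a log2 fold change of -3.06 (SE 0.32, adjusted p = 9.6e-05), 8.35-fold, to 11.05 ± 5.98 CPM, and passed without each library in turn. SGK1 fell with a log2 fold change of -2.17 (SE 0.34, adjusted p = 0.0138), 4.49-fold, to 8.14 ± 4.83 CPM. The adjusted p of SGK1 was 0.105, 0.0520 and 0.0829 without vehicle replicates 2, 3 and 4, and 0.0942 and 0.0812 without URMC-099 replicates 1 and 2. It was 0.0806 by limma voom, in a range of 1.98e-05 to 0.0806 over the alternatives that kept all libraries. The number of genes was 3 without vehicle replicate 1, 1 in each of the 5 fits just named for SGK1, 2 without URMC-099 replicate 3 and 5 without URMC-099 replicate 4.

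Genes next by p did not pass with edgeR, though MTF2, ACBD4, C16orf46, S100A14 and SYTL5 passed by DESeq2. MTF2, a Polycomb subunit gene, went from 45.2 to 24.6 CPM (log2 fold change -0.88, adjusted p = 0.377). ACBD4, a peroxisome tether gene, was at 1.72 CPM with vehicle and 0 counts with URMC-099, at least 46.8-fold lower. C16orf46 was at 2.95 CPM with vehicle and 0 counts with URMC-099, at least 80.5-fold lower. Other genes of this kind were higher as values: S100A14 from 1375 to 1883 CPM (0.45), TCN1 from 55.3 to 95.9 (0.79), SLC37A4 from 17.5 to 31.6 (0.86) and RBL2 by a log2 fold change of 0.64. SYTL5 was at 1.47 CPM with URMC-099, at least 37.4-fold higher than with vehicle, with 0 counts in URMC-099 replicate 3. MAP3K11 stood at 22.3 ± 6.93 CPM (log2 fold change 0.12), MAP3K9 at 3.12 (0.89), MAP3K10 at 2.46 (-0.13) and MAP3K21 at 4.45 (-0.01). MAP3K9 was at 0.37 and 0.54 without URMC-099 replicates 3 and 4, and the sign varied between alternatives for all 4 of them. The list of MLK and neighbouring kinases had a median of -0.06 and a mean of 0.03, tested as lower (adjusted p = 0.727).

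Of the 34 lists, 12 passed with URMC-099 by camera with a preset correlation, 7 higher and 5 lower. With an estimated correlation 0 passed, and fry called 2, the AP-1 list (adjusted p = 0.0246) and the NRF2 list (adjusted p = 0.0246). The AP-1 and immediate-early list had a median of -0.76, with 25 of 27 genes lower (adjusted p = 2.1e-13; adjusted p = 0.226 with an estimated correlation). Of its genes 1 fell after adjustment over all genes and 13 when adjusted over the list alone. FOS, an AP-1 subunit, went from 54.5 ± 24.6 to 6.51 ± 4.75 CPM (-3.06), JUN (chr1:58780788-58784327) from 166 ± 38.3 to 68.8 ± 14.7 (-1.27), EGR1 from 133 to 39.8 ± 10.1 (-1.74; -1.96 with an adjusted p of 0.0239 without vehicle replicate 1) and NR4A2 from 14.9 to 4.92 (-1.59). FOS, JUN and EGR1 passed by DESeq2, JUN also with only the groups compared, FOS and EGR1 also without the robust step, and FOS also with the host marker covariate. The list passed without each library in turn.

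The hypoxia list fell with a median of -0.52 and 23 of 28 genes lower (adjusted p = 2.2e-06; adjusted p = 0.590 with an estimated correlation). The angiogenic factor gene VEGFA went from 190 ± 49.0 to 91.0 ± 27.3 CPM (-1.06) and the lipid droplet gene HILPDA from 221 to 161 (-0.45). The TGF-beta target list fell with a median of -0.46, 16 of 18 genes lower (adjusted p = 0.00279; adjusted p = 0.273 with an estimated correlation). In it the circadian repressor BHLHE40 was lower by a log2 fold change of -0.87 and IGFBP3 by -0.33. The oxidative phosphorylation list rose with a median of 0.23 and 32 of 35 genes higher (adjusted p = 2.2e-07; adjusted p = 0.466 with an estimated correlation). The cytochrome oxidase gene COX6A1 went from 259 to 328 CPM (0.34) and the complex I gene NDUFB2 from 246 to 333 (0.44; 0.24 without URMC-099 replicate 3). No member of these lists passed alone, and the 3 lists passed without each library in turn. None of the hypoxia or oxidative phosphorylation genes is in another list, and 2 of the TGF-beta genes are.

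The fibroblast list, chosen to mark host stroma, fell with a median of -0.55 and 18 of 20 genes lower (adjusted p = 0.000256, or 0.466 with an estimated correlation). The counts are of human genes, and whether mouse reads were removed is not given. The list thus does not measure host cells directly. None of its genes is in another list, and 19 were over 1 CPM with vehicle. The median was -0.26 without vehicle replicate 4, -0.35 without URMC-099 replicate 2 and -0.997 without URMC-099 replicate 4, all past the threshold. With host marker levels as a covariate, which contains this list, it was -0.15 (adjusted p = 0.220). The adjusted p ranged from 0.00015 to 0.466 over the alternatives that kept all libraries. The collagen gene COL3A1 was at 372 ± 199 CPM with vehicle and 204 ± 185 with URMC-099, and COL1A1 at 944 ± 451 and 612 ± 446. Without URMC-099 replicate 4 the means with URMC-099 were 113 and 397 CPM. The mesenchymal and matrix list, of which 2 genes are in another list, fell with a median of -0.33 and 20 of 24 genes lower (adjusted p = 0.000577; adjusted p = 0.285 with an estimated correlation). The transcription factor ZEB2 was lower by a log2 fold change of -0.95 and the tropomyosin gene TPM2 by -0.54, or by -0.21 without vehicle replicate 1, the library highest in muscle genes. With the host marker covariate the mesenchymal median was -0.12 (adjusted p = 0.0234, in a range of 0.000367 to 0.285). The skeletal muscle list had a median of -2.29, or -2.30 with the floor, and 14 of 15 genes lower (adjusted p = 0.0745), which did not pass.

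The remaining lists that rose had small medians, and most depended on single libraries. The mitosis list had a median of 0.20 with 24 of 30 genes higher (adjusted p = 0.0112; adjusted p = 0.661 with an estimated correlation), with the checkpoint kinase gene TTK from 11.2 to 20.3 CPM. It was 0.0652 without vehicle replicate 3 and 0.115 without URMC-099 replicate 1 by adjusted p, and its median was 0.33 without URMC-099 replicate 2. The heat shock list had a median of 0.20 with 16 of 19 genes higher (adjusted p = 0.0112; adjusted p = 0.592 with an estimated correlation), with HSPE1 from 79.0 to 112 CPM. Without vehicle replicates 1 and 3 the adjusted p was 0.0769 and 0.0652, and without URMC-099 replicate 1 it was 0.109, with a median of 0.13. The ribosomal protein list had a median of 0.09 with 34 of 38 genes higher (adjusted p = 0.0112; adjusted p = 0.661 with an estimated correlation), with RPL14 at a log2 fold change of 0.27, or 0.14 without URMC-099 replicate 3. Without vehicle replicate 3 the median was 0.04 (adjusted p = 0.163) and without URMC-099 replicate 3, the library that stood apart, it was 0.00915 (adjusted p = 0.765). It was 0.13 without URMC-099 replicate 1. With the host marker covariate its median was -0.00719 and by limma voom 0.04, neither past the threshold (adjusted p from 0.0103 to 0.846 over the alternatives that kept all libraries).

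The NRF2 list had a median of 0.20 with 14 of 16 genes higher (adjusted p = 0.0142; adjusted p = 0.226 with an estimated correlation) and passed without each library in turn. The transketolase gene TKT was higher by a log2 fold change of 0.27, or 0.14 without URMC-099 replicate 3, and the redox gene NQO1 by 0.32. With no filter on low counts its median was 0.10 (adjusted p = 0.0951, in a range of 0.00644 to 0.226). The interferon list had a median of 0.27 with 21 of 29 genes higher (adjusted p = 0.0173; adjusted p = 0.262 with an estimated correlation). ISG15 went from 11.9 to 17.4 CPM, a log2 fold change of 0.54 that was 0.897 without vehicle replicate 1. In turn without vehicle replicates 1 and 4 the adjusted p was 0.125 and 0.107, and it was 0.109, 0.240 and 0.176 without URMC-099 replicates 1, 2 and 3, with a median of 0.16 and 0.17 without replicates 2 and 3. It did not pass with no filter on low counts, by limma voom or with the host or muscle marker covariate. The medians there were 0.27, 0.23, 0.24 and 0.22, close to the main value. The adjusted p ranged from 0.0089 to 0.296 over the alternatives that kept all libraries. The basal and squamous list had a median of 0.21 with 20 of 24 genes higher (adjusted p = 0.0183; adjusted p = 0.590 with an estimated correlation). SFN was higher by a log2 fold change of 0.43 and the keratin gene KRT16 by 0.47. Leaving out vehicle replicates 1, 2 and 3 in turn gave an adjusted p of 0.134, 0.0823 and 0.127, and it was 0.153, 0.212 and 0.0706 without URMC-099 replicates 1, 2 and 4. With no filter on low counts it was 0.0591 (0.00143 to 0.590). The p53 target list had a median of -0.05 (adjusted p = 0.306), with XPC at a log2 fold change of -0.50. The BCL2 family list had a median of 0.03 (adjusted p = 0.465), with BMF at 3.61 CPM and BIK at a log2 fold change of 1.72. Both signs turned: the p53 median ran from -0.16 without URMC-099 replicate 1 to 0.02 without vehicle replicate 2, and the BCL2 family median from -0.01 without URMC-099 replicate 4 to 0.07 without vehicle replicate 2.

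**Figure D2:**
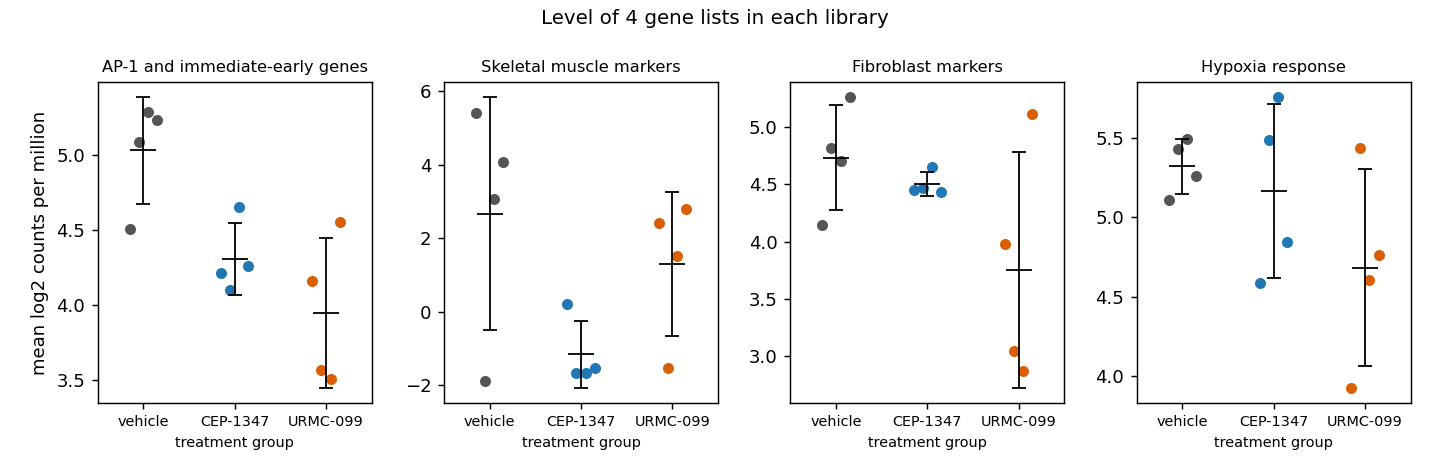
Mean log2 CPM of the AP-1 and immediate-early, skeletal muscle, fibroblast and hypoxia lists in each library of the 3 groups; points are libraries, and lines and bars are the mean ± SD. The AP-1 list is at 5.03 ± 0.36 with vehicle, 4.31 ± 0.24 with CEP-1347 and 3.95 ± 0.50 with URMC-099, and the skeletal muscle list at 2.67 ± 3.18, -1.17 ± 0.91 and 1.29 ± 1.96.

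The third comparison, URMC-099 against CEP-1347, asks how the responses to the 2 inhibitors differ as given. The doses were not equal (7.0 and 1.5 mg/kg), so it compares treatments and not molecules at a matched dose. No single gene differed by edgeR. As groups, skeletal muscle, oxidative phosphorylation, interferon and ribosomal protein genes were higher with URMC-099, and hypoxia, AP-1, mesenchymal, fibroblast and p53 target genes were lower. These calls hold for a preset correlation between genes only: 0 lists passed with an estimated correlation or by fry. Only the skeletal muscle list kept its call without each library in turn, and these fits passed 2 to 9 lists. Of 35 splits of the same libraries, the real one included, 7 passed at least the 9 lists found here. The other splits passed 5.32 on average, so chance is not excluded for this number of lists.

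With edgeR, 0 genes passed between the inhibitors, with 668 at an unadjusted p under 0.05, 317 higher and 351 lower with URMC-099, against 820 by chance. DESeq2 called 4 genes and limma voom 0. The libraries did not overlap for 195 genes higher and 229 lower, against 234 by chance in each direction. The smallest p was that of TCN1 (ENSG00000134827.7, chr11:59852800-59866575), which encodes a vitamin B12 binding protein. It was at 43.6 ± 8.78 CPM with CEP-1347 and 95.9 ± 31.3 with URMC-099, a log2 fold change of 1.14 (95% interval 0.72 to 1.55, adjusted p = 0.154). Without URMC-099 replicate 3, TCN1 was the 1 gene that passed (log2 fold change 1.30, adjusted p = 0.00505). For TCN1 the adjusted p was 0.00636 with no filter on low counts and 0.00250 by DESeq2, in a range of 0.00250 to 0.9997 over the alternatives that kept all libraries. Among the next genes as values, the receptor gene IL17RC was higher with URMC-099 by 0.63, OAZ2 by 0.41 and DPYSL3 by 0.75, while AKAP8L was lower by -0.75 and AKIRIN1 by -0.56. ACBD4 and C16orf46, with 0 counts with URMC-099, were at least 40.6-fold and at least 30.9-fold lower than with CEP-1347, and ACBD4 passed by DESeq2. The bound was 26.9-fold for ACBD4 without CEP-1347 replicate 3 and 8.91-fold for C16orf46 without CEP-1347 replicate 4, and C16orf46 had 0 counts in CEP-1347 replicates 2 and 3 as well.

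Genes that were lower with both inhibitors than with vehicle were also compared directly. The log2 fold change of NR4A1 between the inhibitors was -0.77 (95% interval -1.39 to -0.15, adjusted p = 1.0), that of SGK1 -0.34 (-1.03 to 0.34), that of EGR1 -0.30 (-1.04 to 0.44), that of JUN -0.66 (-1.23 to -0.10) and that of FOS -1.45 (-2.82 to -0.08). None passed. JUN was at -0.32 without CEP-1347 replicate 3 and NR4A1 at -1.20 without URMC-099 replicate 4. With the host marker covariate NR4A1 was at -0.38 and FOS at -0.81. MAP3K11 differed by 0.04 (-0.53 to 0.62), MAP3K9 by 0.97, MAP3K10 by -0.12 and MAP3K21 by 0.36. MAP3K9 was at 0.44 and 0.61 without URMC-099 replicates 3 and 4, and MAP3K21 ran from 0.12 without URMC-099 replicate 2 to 0.66 without CEP-1347 replicate 4. The signs of MAP3K10 and MAP3K11 varied between alternatives. The list of MLK and neighbouring kinases had a median of -0.00277 and a mean of 0.13 (adjusted p = 0.760).

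By camera with a preset correlation 9 lists differed between the inhibitors, 4 higher and 5 lower with URMC-099, and no member passed alone. With an estimated correlation and by fry 0 passed. The skeletal muscle list was higher with a median of 3.38, or 3.39 with the floor, and 15 of 15 genes higher (adjusted p = 9.0e-06; adjusted p = 0.704 with an estimated correlation). TTN was at 0.472 CPM with CEP-1347, or 0.0782 without CEP-1347 replicate 1, and 17.4 with URMC-099. The median was 5.56 without CEP-1347 replicate 1, and the call ended with the muscle marker covariate, which is built from this list (-0.21). The hypoxia list was lower with a median of -0.43 and 24 of 28 genes lower (adjusted p = 0.000239; adjusted p = 0.708 with an estimated correlation), with the kinase gene AK4 at a log2 fold change of -0.86 and VEGFA at -0.90. Hypoxia had a median of -0.21 (adjusted p = 0.0842) without CEP-1347 replicate 3, where AK4 was at -0.56, and an adjusted p of 0.118 without URMC-099 replicate 1. Its median was -0.67 without URMC-099 replicate 2. With the muscle marker covariate the median was -0.22 (adjusted p = 0.441, in a range of 8.0e-07 to 0.708 over the alternatives that kept all libraries). The oxidative phosphorylation list was higher with a median of 0.12 and 29 of 35 genes higher (adjusted p = 0.000847; adjusted p = 0.708 with an estimated correlation), with COX6A1 at 265 and 328 CPM. Oxidative phosphorylation had a median of 0.07 (adjusted p = 0.246) without CEP-1347 replicate 3, and an adjusted p of 0.0722 without URMC-099 replicate 3. Its median was 0.23 without CEP-1347 replicate 1 and 0.07 without URMC-099 replicate 1. With the muscle marker covariate it was 0.07 (adjusted p = 0.0566, in a range of 0.000184 to 0.708).

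The AP-1 list was lower with a median of -0.27 and 21 of 27 genes lower (adjusted p = 0.00545; adjusted p = 0.704 with an estimated correlation). Without CEP-1347 replicate 3 the adjusted p was 0.195, and it was 0.0571 and 0.133 without URMC-099 replicates 2 and 3. The AP-1 median was -0.11 with the host marker covariate (adjusted p = 0.518) and -0.22 with the muscle marker covariate (adjusted p = 0.0566), in a range of 0.000648 to 0.704 over the alternatives that kept all libraries. The mesenchymal list was lower with a median of -0.23 and 19 of 24 genes lower (adjusted p = 0.00545; adjusted p = 0.704 with an estimated correlation), with SNAI2 at -0.39. Mesenchymal genes had an adjusted p of 0.0535 without URMC-099 replicate 3, and a median of -0.12 and -0.37 without URMC-099 replicates 1 and 4. With the host marker covariate the median stayed at -0.23, but the adjusted p was 0.483 (0.00393 to 0.704). The fibroblast list had a median of -0.05 with 12 of 20 genes lower (adjusted p = 0.00764; adjusted p = 0.704 with an estimated correlation), with the matrix gene DCN at 1.89 and 0.247 CPM (0.0767 without URMC-099 replicate 4). Its median was 0.07 with the host marker covariate, which contains this list. It was -0.02 with the filter at a mean of 50 counts and -0.09 by limma voom, and none of these 3 passed the threshold. With the muscle marker covariate it was -0.13, past it (adjusted p from 0.0036 to 0.994 over the alternatives). Without URMC-099 replicate 2 the median was -0.01 (adjusted p = 0.123), and the adjusted p was 0.0722 without URMC-099 replicate 3, where the median was 0.00. Its median was -0.12, -0.08 and -0.13 without CEP-1347 replicates 1, 2 and 4, and -0.09 and -0.59 without URMC-099 replicates 1 and 4.

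The interferon list was higher with a median of 0.27 and 23 of 29 genes higher (adjusted p = 0.00764; adjusted p = 0.419 with an estimated correlation), with IFI6 at 5.05 CPM with CEP-1347 and 12.8 ± 13.1 with URMC-099, a log2 fold change of 1.33 that was 0.30 without URMC-099 replicate 3. Without CEP-1347 replicate 2 the adjusted p was 0.127, and it was 0.0975 and 0.0535 without URMC-099 replicates 2 and 3, and its median was 0.17 and 0.40 without CEP-1347 replicates 1 and 4. It was 0.18 with the host marker covariate (adjusted p = 0.124) and 0.40 with the muscle marker covariate (adjusted p = 0.00575), in a range of 0.00575 to 0.604. The ribosomal protein list had a median of 0.07 with 33 of 38 genes higher (adjusted p = 0.00838; adjusted p = 0.856 with an estimated correlation), with RPL3 at 0.28, or 0.14 without URMC-099 replicate 3. Without CEP-1347 replicate 4 the median was 0.03 (adjusted p = 0.211), and the adjusted p was 0.935 without URMC-099 replicate 3, where the median was -0.00904. Its median was 0.12 without CEP-1347 replicate 2, 0.11 without URMC-099 replicate 2, 0.13 without URMC-099 replicate 4 and -0.000504 with the host marker covariate. That setting and limma voom (0.05) ended the call (adjusted p from 0.00746 to 0.939). The p53 target list, of which 4 genes are in another list, was lower with a median of -0.21 and 20 of 24 genes lower (adjusted p = 0.0134; adjusted p = 0.704 with an estimated correlation), with XPC at -0.53 and the death receptor gene TNFRSF10B at -0.50. Its adjusted p was 0.246 and 0.0753 without CEP-1347 replicates 3 and 4 and 0.0535 and 0.163 without URMC-099 replicates 3 and 4, and its median was -0.10 without CEP-1347 replicate 3 and also without URMC-099 replicate 3, and -0.32 without URMC-099 replicate 2. With the muscle marker covariate it was -0.11 (adjusted p = 0.440, in a range of 0.00282 to 0.704). The mitosis list had a median of -0.00269 and a mean of 0.05, tested as higher (adjusted p = 0.540), with TTK at 0.55, and ran from -0.13 without CEP-1347 replicate 3 to 0.10 without CEP-1347 replicate 1. The BCL2 family list had a median of -0.10 (adjusted p = 0.367), with BIRC3, an inhibitor of apoptosis, at -2.48. Without URMC-099 replicate 2 these were -0.03 and -3.9. The number of lists that passed was 5 without CEP-1347 replicate 3 and 2 without URMC-099 replicate 3.

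The fourth comparison, the mean of both inhibitor groups against vehicle, asks how the treated tumours differ from vehicle on average. Of the 12 lists it called with a preset correlation, only the AP-1 and heat shock lists were also called with each inhibitor alone. NR4A1 and SGK1 fell, in every fit that left out 1 library as well. AP-1 and immediate-early, hypoxia, TGF-beta, fibroblast, mesenchymal and skeletal muscle genes fell as groups, and heat shock, oxidative phosphorylation, NRF2, mitosis, basal epithelial and G1/S genes rose as groups by small amounts. With an estimated correlation between genes 0 of these lists passed, and the fibroblast, mesenchymal, mitosis, basal and G1/S lists lost their call without some single libraries.

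With edgeR, 2 genes passed, 0 higher and 2 lower, with 798 at an unadjusted p under 0.05, 321 higher and 477 lower. DESeq2 called 15 genes and limma voom 5. The vehicle and treated libraries did not overlap for 24 genes higher and 40 lower, against 33.1 by chance in each direction. NR4A1 fell with a log2 fold change of -2.68 (SE 0.24, adjusted p = 1.2e-05), 6.39-fold, and SGK1 with -2.00 (SE 0.27, adjusted p = 0.00145), 3.99-fold. The number of genes was 5 without CEP-1347 replicate 3 and 14 without URMC-099 replicate 4, and 2 or 3 without any other library. EGR1 (-1.59, adjusted p = 0.261), TNS1 (-1.05, adjusted p = 0.261) and RTN2, an endoplasmic reticulum gene at 21.6 ± 15.9 CPM with vehicle and 4.82 and 4.95 with CEP-1347 and URMC-099, or 3.27 without URMC-099 replicate 4 (-2.14, adjusted p = 0.261), did not pass. RTN2 stood at 41.2, 4.72, 13.8 and 26.6 CPM in vehicle replicates 1 to 4, in the order of the skeletal muscle list, and its log2 fold change was -0.77 with the muscle marker covariate. NACC1 did not pass either (1.16, adjusted p = 0.271). By DESeq2 all 4 of these passed, as did JUN and FOS. TNS1 also passed with no filter on low counts, and EGR1 and FOS by limma voom, without the robust step and with the host marker covariate. Leaving out 1 library let some of them pass with edgeR: EGR1 without vehicle replicate 1 (adjusted p = 0.00576) and CEP-1347 replicate 3 (0.0332), TNS1 without CEP-1347 replicate 3 (0.0332) and URMC-099 replicate 4 (0.00928), and RTN2 without vehicle replicate 2 (0.00942) and URMC-099 replicate 4 (0.00929). JUN passed without CEP-1347 replicate 3 (adjusted p = 0.00312) and KLF4 without URMC-099 replicate 4 (0.00929). MAP3K11 was at 0.10, MAP3K9 at 0.41, MAP3K10 at -0.07 and MAP3K21 at -0.20. MAP3K9 was at 0.15 without URMC-099 replicate 3, and the signs of MAP3K9, MAP3K10 and MAP3K11 varied between alternatives.

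The log2 fold changes of the 2 inhibitors against vehicle correlated across the 16406 genes with r = 0.532. Genes are not independent replicates, and the vehicle libraries are shared: simulated groups without any change gave r = 0.501 (0.480 to 0.523). The covariance was 0.263 against 0.220 simulated. With the vehicle libraries split 2 and 2, so that nothing is shared, the mean r over 6 assignments was 0.0571 (0.0391 to 0.0890). The simulated value was 0.000266. The simulated genes are independent, which real genes are not. The simulated values therefore do not show how far chance moves r or the covariance in real data. The 1 gene called lower with both was NR4A1, against 0.000122 expected for independent lists and 0 in 20 simulations that kept the shared vehicle libraries. In 4 of the 6 assignments NR4A1 passed in both comparisons.

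By camera with a preset correlation 12 lists passed, 6 higher and 6 lower. With an estimated correlation 0 passed, and fry called the AP-1 list (adjusted p = 0.0369) and the NRF2 list (adjusted p = 0.0369). The AP-1 list had a median of -0.59, with 25 of 27 genes lower (adjusted p = 1.6e-13; adjusted p = 0.196 with an estimated correlation). Of its genes 1 fell after adjustment over all genes and 13 when adjusted over the list alone. FOS was lower by -2.33, KLF4 by -1.76, NR4A2 by -1.26 and JUN by -0.94. The heat shock list had a median of 0.25 with 18 of 19 genes higher (adjusted p = 0.00047; adjusted p = 0.408 with an estimated correlation), with STIP1 at 0.39 and HSP90AA1 at 0.32. The NRF2 list had a median of 0.15 with 13 of 16 genes higher (adjusted p = 0.0109; adjusted p = 0.196 with an estimated correlation), with AKR1C3 at 1.05 and TXN at 0.36, or 0.20 without vehicle replicate 3. These 3 lists passed without each library in turn. With no filter on low counts the NRF2 list had an adjusted p of 0.102 (0.00426 to 0.196 over the alternatives that kept all libraries).

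The skeletal muscle list fell with a median of -4.19 and 15 of 15 genes lower (adjusted p = 1.0e-06; adjusted p = 0.408 with an estimated correlation). Of its genes 0 fell after adjustment over all genes and 10 when adjusted over the list alone. Its median was -2.68 without vehicle replicate 1, -2.63 by limma voom and 0.46 with the muscle marker covariate, which is built from this list. The hypoxia list fell with a median of -0.30 and 23 of 28 genes lower (adjusted p = 0.00047; adjusted p = 0.620 with an estimated correlation), with HILPDA at -0.26, or -0.15 without vehicle replicate 2, and the pyruvate dehydrogenase kinase gene PDK1 at -0.45. Its median was -0.19 without CEP-1347 replicate 1 and also without URMC-099 replicate 1, and -0.46 without URMC-099 replicate 2. With the muscle marker covariate it was -0.65, past the threshold. The TGF-beta list fell with a median of -0.31 and 17 of 18 genes lower (adjusted p = 0.00308; adjusted p = 0.376 with an estimated correlation), with BHLHE40 at -0.66 and ID2 at -0.62. Its median was -0.47 without vehicle replicate 1. The fibroblast list fell with a median of -0.45 and 18 of 20 genes lower (adjusted p = 0.00552; adjusted p = 0.469 with an estimated correlation), with COL1A1 at -0.69, or -0.44 without vehicle replicate 2. Without vehicle replicate 4 its median was -0.13 (adjusted p = 0.125), and it was -0.73 without vehicle replicate 1 and -0.75 without URMC-099 replicate 4. With the host marker covariate, which contains this list, it was -0.16 (adjusted p = 0.134). With the muscle marker covariate it was -0.28 (adjusted p = 0.115), in a range of 0.00361 to 0.475. The mesenchymal list fell with a median of -0.24 and 17 of 24 genes lower (adjusted p = 0.0109; adjusted p = 0.408 with an estimated correlation), with ZEB2 at -0.79. Mesenchymal genes had an adjusted p of 0.0713 without vehicle replicate 4, and their median was -0.14 without CEP-1347 replicate 1 and also without URMC-099 replicate 1.

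The oxidative phosphorylation list rose with a median of 0.18 and 31 of 35 genes higher (adjusted p = 2.28e-05; adjusted p = 0.439 with an estimated correlation), with ATP5PF at 0.35 and CYC1 at 0.25. Its median was 0.11 without vehicle replicate 3. The mitosis list rose with a median of 0.14 and 24 of 30 genes higher (adjusted p = 0.00853; adjusted p = 0.620 with an estimated correlation), with KIF2C at 0.60. Mitosis genes had an adjusted p of 0.0769 and 0.0643 without vehicle replicates 3 and 4, and a median of 0.09 without CEP-1347 replicate 1 and 0.22 with the muscle marker covariate. The basal list rose with a median of 0.21 and 18 of 24 genes higher (adjusted p = 0.0165; adjusted p = 0.439 with an estimated correlation), with SFN at 0.36. Basal genes had an adjusted p of 0.163, 0.102 and 0.134 without vehicle replicates 1, 2 and 3, 0.193 without CEP-1347 replicate 2, and 0.0835, 0.132 and 0.0529 without URMC-099 replicates 1, 2 and 4. With no filter on low counts it was 0.0528 (0.00253 to 0.540). The G1/S list rose with a median of 0.08 and 24 of 34 genes higher (adjusted p = 0.0391; adjusted p = 0.641 with an estimated correlation), with the thymidine kinase gene TK1 at 0.49 and E2F1 at 0.38. Its adjusted p was 0.0969 and 0.115 without vehicle replicates 3 and 4, 0.254 and 0.0971 without CEP-1347 replicates 1 and 2, and 0.102 and 0.0660 without URMC-099 replicates 1 and 4. Its median was 0.04 without CEP-1347 replicate 1, 0.14 without vehicle replicate 2, 0.16 without CEP-1347 replicate 3, and 0.13 and 0.12 without URMC-099 replicates 2 and 3. The call also ended with no filter (adjusted p = 0.0509) and with the filter at a mean of 50 counts (adjusted p = 0.0794), in a range of 0.00663 to 0.650.

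**Figure D3:**
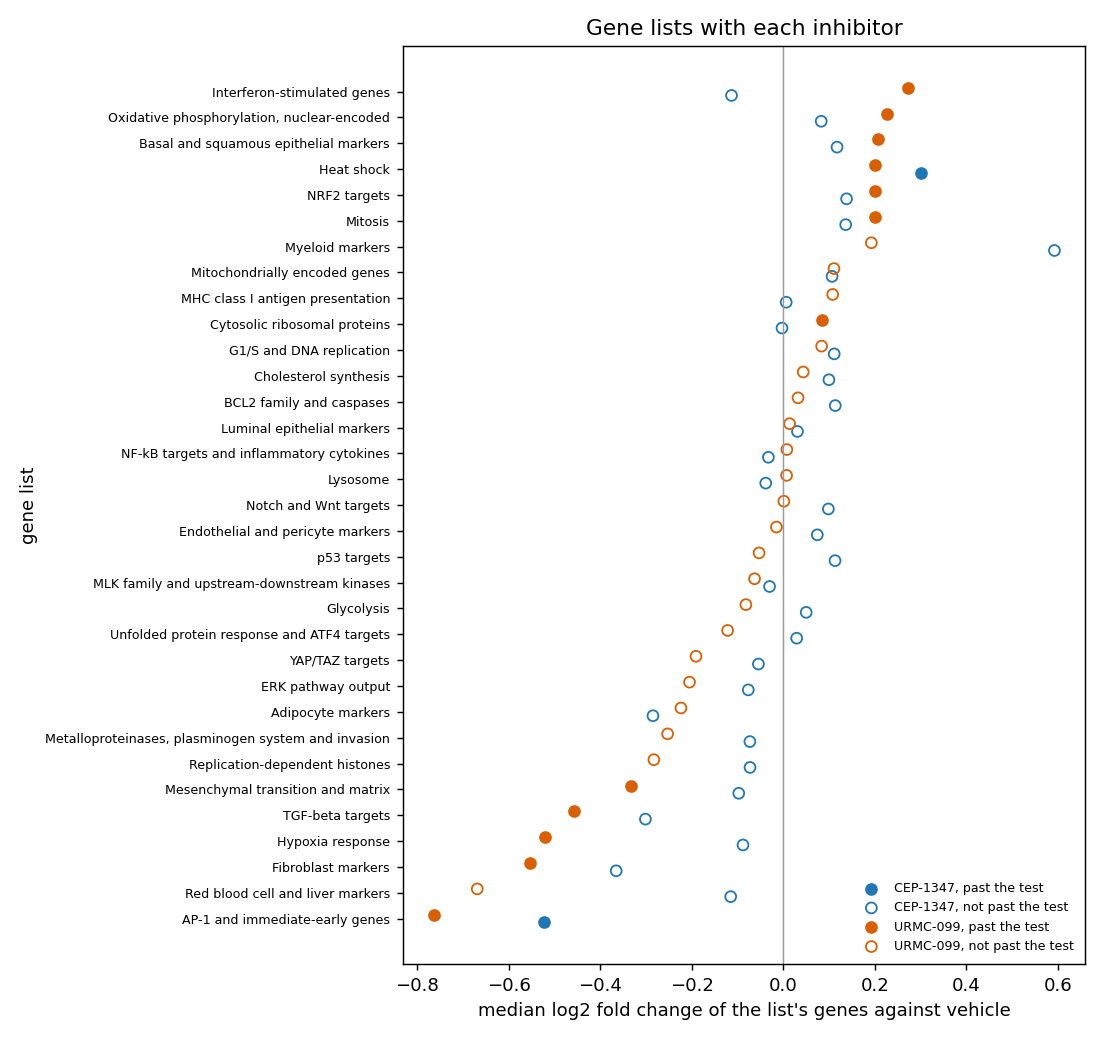
Median log2 fold change of 33 gene lists with CEP-1347 and with URMC-099 against vehicle (x axis), one list per line (y axis); each point is a list in 1 comparison, and filled points have a camera adjusted p under 0.05 with a preset correlation. The skeletal muscle list is left out because its medians (-5.56 and -2.29) lie far off the scale; the AP-1 list lies at -0.52 with CEP-1347 and -0.76 with URMC-099.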

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

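The tests of tissue handling and of fewer host cells, the muscle marker covariate and the second muscle list were chosen only after the results were seen. The other tests in this part were written before their results.

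The first pattern is the fall of the AP-1 and immediate-early genes in both inhibitor groups, with a list median of -0.59, 25 of 27 genes lower and NR4A1 passing alone. For both inhibitors against vehicle the list passed with a preset correlation between genes and by fry. It did not pass with an estimated correlation (adjusted p = 0.196, in a range of 2.4e-19 to 0.196 over the alternatives that kept all libraries). With CEP-1347 alone 0 lists passed by fry. With muscle marker levels as a covariate the median was -0.72 (adjusted p = 3.2e-12), which argues against muscle carried over into the vehicle pieces as the cause. Lower host stroma cannot be told apart. With host marker levels as a covariate the median was -0.44 (camera, adjusted p = 7.8e-13). Its distance from the bound set beforehand is within a spread of 0.198. That spread is the SD of the median over 2000 draws of the list's genes in the fit without the covariate. It does not measure variation between tumours. Tissue handling at collection cannot be told apart either, because no order of collection is given, and the heat shock list, which handling also moves, stood at 0.25. An effect of the inhibitors themselves, the difference the design names, stays open and was not tested further.

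The second pattern is the level of skeletal muscle genes, high in vehicle replicates 1, 3 and 4 and low with CEP-1347 (list median -5.56). A candidate explanation is muscle tissue in the dissected pieces, which would bring all abundant muscle transcripts. A second list of skeletal muscle genes had a median of -0.48 with CEP-1347, or -0.49 with the floor, with 13 of 18 genes lower and a spread of 0.296 (camera p = 0.0150 with the preset and p = 0.124 with an estimated correlation, unadjusted). The bound set against muscle tissue was a median within 0.5 of zero. These values lie inside it by less than the spread, which is again over draws of genes and not over tumours. The explanation thus cannot be told apart from a treatment effect. Among its genes MYOZ1 was at 6.52 CPM with vehicle (2.92 without vehicle replicate 1) and 0.170 with CEP-1347 (0.0429 without CEP-1347 replicate 2), and CASQ1 at 4.14 (1.68 without vehicle replicate 1) and 0.406 (0.186 without CEP-1347 replicate 4), while TPM3 was at 79.8 and 88.9.

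The third pattern is the fall of the fibroblast and mesenchymal lists with URMC-099 (medians -0.55 and -0.33; adjusted p = 0.466 and 0.285 with an estimated correlation). Low complexity of single libraries cannot be told apart. The fibroblast median was -0.50 with only genes of a mean of at least 50 counts and -0.48 without URMC-099 replicate 3. Both passed the threshold and met the prediction written against low complexity. That test left out replicate 3 only. URMC-099 replicates 1 and 2 also had 48 and 68 genes at 0 with a mean of at least 50 counts elsewhere, against 8 in replicate 4. Without URMC-099 replicate 4 the fibroblast median was -0.997. With host marker levels as a covariate the medians were -0.15 (adjusted p = 0.220, in a range of 0.000150 to 0.466) and -0.12 (adjusted p = 0.0234, in a range of 0.000367 to 0.285), but that covariate contains the fibroblast list itself. Fewer host cells would lower other host lists too. The endothelial and pericyte median was -0.0147 (mean -0.09, tested as higher) and the myeloid median 0.19, but the SD over the myeloid genes was 2.01. A lower host share thus cannot be told apart from a change in the fibroblasts or the tumour cells. All these lists are of human genes, so they do not measure mouse cells directly. The treatment stays open and untested.

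Other splits of the same libraries show how often chance gives as large a result. For the genes changed with CEP-1347, 1 of 35 splits gave as many (real 1, highest other 0), the smallest share that 35 splits allow. For both inhibitors against vehicle 4 of 100 drawn splits did (real 2, highest other 13). These shares are under 5% before any adjustment for the number of split tests, so they do not exclude chance on their own. For the AP-1 median of both inhibitors 2 of 100 splits were as large (real -0.59, highest other 0.64 in size), also under 5% without adjustment. The share was over 5% for the AP-1 median with CEP-1347, 2 of 35 splits (real -0.52, highest other 0.72), and with URMC-099, 2 of 35 (real -0.76, highest other 0.82). In these splits vehicle replicate 1 stood with the treated libraries. The share was also over 5% for the genes with URMC-099, 4 of 35 (real 2, highest other 11). Between the inhibitors the real number of genes was 0 (highest other 2). All 35 of 35 splits give at least as many by construction, so this test cannot decide. For the number of lists, 27 of 35 splits gave as many with CEP-1347 (real 3, highest other 13) and 3 of 35 with URMC-099 (real 12, highest other 12). Between the inhibitors it was 7 of 35 (real 9, highest other 14), and for both against vehicle 5 of 100 (real 12, highest other 16). These shares are 5% or more, so chance is not excluded for the number of lists in any comparison. The other splits passed 5.71, 4.68, 5.32 and 5.23 lists on average, in the same order. Splits that call several times the real number of genes can point to a structure of the samples, which was not tested here. The split with 11 genes set vehicle replicate 1 with URMC-099 replicates 1 to 3 and so kept most treatment labels, so its calls can come from the treatment. The split with 13 set vehicle replicates 2 and 4, CEP-1347 replicate 1 and URMC-099 replicate 4 against the rest.

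Of 453 groups of 4 values tested for 1 library far from the other 3 by Dixon's test, 32 had one, against 22.7 by chance at 1 in 20. In URMC-099 replicate 3, pseudogenes took 11.8% of the counts, against 9.55% to 9.77% in the rest of its group, and IFI6 was at 32.4 CPM against 5.07 to 7.78. In URMC-099 replicate 4, JUN was at 90.7 CPM against 59.6 to 62.7, ZEB2 at 26.3 against 9.55 to 12.2 and COL3A1 at 478 against 78.2 to 143. In URMC-099 replicate 2, the heat shock list was at a mean log2 CPM of 6.66 against 6.93 to 6.98, HSPE1 at 105 CPM against 114 to 116, TXN at 98.5 against 182 to 192 and PER1 at 60.2 against 35.1 to 37.4. In URMC-099 replicate 1, P4HA2 was at 26.3 CPM against 15.5 to 16.9 and DHRS7C at 4.28 against 0 to 0.637.

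In CEP-1347 replicate 1, the skeletal muscle list was at a mean log2 CPM of 0.20 against -1.67 to -1.54, with TTN at 1.65 CPM against 0 to 0.184, NEB at 0.361 against 0 to 0.0612, and DHRS7C and MYH2 at 0.0516, a single count each, against 0. MTF2 was at 45.8 CPM there against 38.6 to 39.8. In CEP-1347 replicate 2, the interferon list was at 0.59 against 1.44 to 1.61 and the myeloid list at -1.70 against -0.38 to -0.12. In CEP-1347 replicate 3, the mitosis list was at 4.76 against 5.31 to 5.42, TNS1 at 29.8 CPM against 17.3 to 18.6, KLF4 at 8.88 against 3.36 to 4.27, COX6A1 at 219 against 276 to 285 and NDUFB2 at 188 against 290 to 303. In CEP-1347 replicate 4, MYLPF was at 0.762 CPM against 0 to 0.0516.

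In vehicle replicate 1, TPM2 was at 133 CPM against 60.4 to 71.1, ID2 at 10.1 against 23.2 to 24.6, FKBP5 at 44.2 against 23.04 to 25.9 and P4HA2 at 25.3 against 21.0 to 21.2. In vehicle replicate 2, AKIRIN1 was at 51.7 CPM against 59.9 to 61.6. In vehicle replicate 4, STIP1 was at 153 CPM against 133 to 136 and ACBD4 at 2.37 against 1.46 to 1.56. The lists that differed between the inhibitors in the direct test stand out as well, with medians of 3.38 for skeletal muscle, 0.27 for interferon, 0.12 for oxidative phosphorylation, 0.0713 for ribosomal proteins, -0.43 for hypoxia, -0.27 for AP-1, -0.23 for mesenchymal genes, -0.21 for p53 targets and -0.0522 for fibroblasts.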

How the results depend on the processing

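The muscle marker covariate and the fit of protein-coding genes only were chosen after seeing the data. Across all alternatives 4219 values of single genes kept their direction and side of the threshold, 40 passed newly, 11 no longer passed and 43 reversed. Of the values of single lists 681 kept both, 6 passed newly, 148 no longer passed and 17 reversed, and of the counts 102 stayed within 1.5 times and 48 moved. With RLE size factors no count of genes or lists moved. The number of genes with CEP-1347 was 2 with no filter on low counts, 6 by DESeq2, 3 by limma voom, 2 without robust dispersion, 4 with the host marker covariate, 0 with the muscle marker covariate and 4 with only the groups compared. With URMC-099 it was 24 by DESeq2, 1 by limma voom and 4 without robust dispersion; between the inhibitors 1 with no filter and 4 by DESeq2; and for both against vehicle 15 by DESeq2, 5 by limma voom, 5 without robust dispersion and 6 with the host marker covariate. The number of lists with CEP-1347 was 12 by limma voom, 7 with the muscle marker covariate and 6 with only the groups compared, and between the inhibitors 4 with either covariate. It was 0 in all 4 comparisons with an estimated correlation, and by fry it was 0, 2, 0 and 2. The following values reversed. By limma voom, MAP3K10 with CEP-1347 was 0.159, MAP3K9 was -0.0985 with URMC-099 and -0.256 for both, and MAP3K11 between the inhibitors was -0.0423. With the host marker covariate, MAP3K11 was -0.0711 with URMC-099 and -0.155 between the inhibitors, MAP3K21 with URMC-099 was 0.0163, the ribosomal list was -0.00719 with URMC-099 and -0.000504 between the inhibitors, and the fibroblast list between the inhibitors was 0.0735. With the muscle marker covariate, MAP3K9 was 0.113 and ZMAT3 -0.0823 with CEP-1347, and MAP3K10 was 0.386 and MAP3K11 -0.0677 between the inhibitors. For both against vehicle that covariate also gave 0.462 for NEB, 0.535 for TTN and 0.462 for the skeletal muscle list, which follows from its construction from that list. The camera direction of the p53 list turned, though its median did not: for both against vehicle the median was 0.0609 with the filter at a mean of 50 counts, 0.0416 by limma voom, 0.0181 and 0.00262 with the host and muscle marker covariates, 0.0521 with protein-coding genes and 0.0555 by fry, and with CEP-1347 it was 0.0241 with the muscle marker covariate. The correlation of the responses was 0.0571 with the vehicle libraries split 2 and 2, because nothing is then shared, and the covariance was 0.0406. With genes of a mean of at least 50 counts the covariance was 0.105. Leaving out 1 library gave 0 to 1 genes with CEP-1347, 1 to 5 with URMC-099, 0 to 1 between the inhibitors and 2 to 14 for both, and 3 to 11 lists with CEP-1347 and 2 to 9 between the inhibitors. It gave MAP3K9 with CEP-1347 from -0.405 to 0.214 and MAP3K21 with URMC-099 from -0.250 to 0.173. MAP3K10 ran from -0.322 to 0.618 with CEP-1347, -0.465 to 0.496 with URMC-099, -0.384 to 0.557 for both and -0.459 to 0.208 between the inhibitors. MAP3K11 ran from -0.129 to 0.251, -0.0559 to 0.295, -0.0618 to 0.273 and -0.146 to 0.265 in the same order. The p53 list ran from -0.0300 to 0.0983 for both and the mitosis list from -0.127 to 0.102 between the inhibitors. Except where a construction is named above, the cause was not tested. The list tests do not use the dispersion, so the robust step has no list values, and for both against vehicle a fit of only the groups compared is the same fit. No paired analysis was possible because the labels give no replicate numbers shared between groups. Depth limits the low genes: MAP3K9, MAP3K10 and MAP3K21, at 1.59 to 4.49 CPM, and a value under the floor of 0.130 to 0.201 CPM in a library rests on fewer than 3 counts.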

Other observations

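The 4 gene lists tested here, of glucocorticoid targets, of clock genes in 2 phases and of further muscle genes, were chosen after the results of the comparisons were seen.

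The lists in this paragraph did not pass for both inhibitors against vehicle. The list of MLK and neighbouring kinases had a median log2 fold change of -0.06 (camera, adjusted p = 0.524), ERK output -0.33 (0.324) and YAP/TAZ targets -0.12 (0.324). NF-kB targets had a median of -0.10 and a mean of 0.16 (0.939), metalloproteinases -0.10 (0.389), and Notch and Wnt targets a median of -0.01 and a mean of 0.01 (0.630). The p53 targets were at 0.06 (0.959), the BCL2 family at 0.03 (0.113), the interferon genes at a median of 0.05 and a mean of -0.02 (0.193) and MHC class I at 0.05 (0.193). Leaving out 1 library took the p53 median from -0.03 without vehicle replicate 4 to 0.10 without vehicle replicate 2, and that of the BCL2 family from 0.00339 without URMC-099 replicate 1 to 0.06 without vehicle replicate 2. Camera tested interferon, NF-kB, Notch and Wnt, histone and endothelial genes as higher and the lysosome as lower, each against the sign of its median, its mean or both.

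Nor did metabolic and structural lists pass for both inhibitors. Glycolysis was at -0.01 (adjusted p = 0.897), cholesterol synthesis at 0.11 (0.0992), the lysosome at a median of 0.02 and a mean of -0.02 (1.0), the unfolded protein response and ATF4 targets at -0.05 (0.362), mitochondrially encoded genes at 0.08 (0.0544), ribosomal proteins at 0.04 (0.119), luminal markers at -0.01 (0.959) and histones at -0.14 (0.959). Of the host lists, endothelium and pericytes were at a median of 0.07 and a mean of -0.18 (0.767), with 9, 8 and 9 of 10 genes over 1 CPM with vehicle, CEP-1347 and URMC-099. Myeloid markers were at 0.18 (0.324), with 3, 4 and 1 of 9 genes over 1 CPM, adipocytes at -0.46 (0.113), and red blood cells and liver at -0.91 (0.113). The lymphocyte list, with 4 of 21 genes tested, had a mean log2 CPM of 0.25 ± 0.74 with vehicle, 0.45 ± 0.75 with CEP-1347 and 0.61 ± 0.52 with URMC-099. The xenobiotic list, with 4 of 14 genes tested, was at 2.86 ± 0.28, 2.36 ± 0.24 and 2.37 ± 0.09.

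SGK1 and PER1 respond to glucocorticoids, and PER1 is also a clock gene. For both inhibitors against vehicle SGK1 fell, and PER1 had a log2 fold change of -0.56, from 69.6 CPM with vehicle to 52.6 with CEP-1347 and 42.4 with URMC-099. A lower glucocorticoid response may account for both. Other glucocorticoid targets, of which 3 are in the lists above, had a median of -0.30 with 14 of 18 genes lower (camera p = 0.0292, unadjusted; p = 0.144 with an estimated correlation), with TSC22D3 at -0.53, ERRFI1 at -0.79, CEBPD at -0.48 and KLF9 at -0.41, and FKBP5 at -0.01. The list median was -0.12 with CEP-1347, 12 of 18 genes lower, and -0.30 with URMC-099, 13 of 18 lower. With CEP-1347 the list did not pass by camera with the preset correlation even unadjusted, while SGK1 had a log2 fold change of -1.82. The values this hypothesis needs are there with the preset correlation only, and not with CEP-1347 alone. A different clock phase at collection may also account for them: clock genes of the PER phase had a median of -0.52 with 6 of 6 genes lower (camera p = 0.00546; p = 0.0440 with an estimated correlation), with TEF at -0.59 and NR1D1 at -0.66. Genes of the opposite ARNTL phase had a median of 0.04, with 3 of 5 higher. Camera tested them as lower, against the sign of the median and in the direction of the PER phase (p = 0.504, or p = 0.608 with an estimated correlation). They had a median of -0.29 with URMC-099, 5 of 5 lower (p = 0.190; p = 0.324 with an estimated correlation), and of 0.17 with CEP-1347, 3 of 5 higher (p = 0.868 with an estimated correlation). With URMC-099 both phases thus stood lower, against a shift of phase, though with 5 genes and these p the shift cannot be told apart from a lower level of the PER phase genes, and the time of collection is not given in the sources used here.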
